A study of Homo sapiens with 15 samples.

How the data were processed

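Total RNA of normal human melanocytes, of the melanoma lines WM1552C and A375 and of both lines with overexpressed miR-211 had been hybridised to Affymetrix exon arrays. Per the labels' protocols the cells grew in standard media, the RNA was taken with Trizol, and biotinylated cRNA was made from it. The parental lines served as controls of the miR-211 cultures. The values used were the deposited log2 signals of 17881 transcript clusters on 15 arrays; no raw scanner data, detection flags, scan dates or slide positions were held. How probes were summarised and normalised is not given in the sources used here. The deposited log2 values ran from 4.00 to 16.65 with 0 missing, and every array had its minimum just above 4, the log2 of 16. This matches a constant of 16 added to a linear signal, which no source states, and it would make the changes of weak genes smaller than they were. Array medians ran from 7.02 to 7.75, so the deposited values do not have equal medians.

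Gene names came from the platform's probe table: 14432 clusters had 1 symbol, 2408 had several and were not named, and 1041 were not in that table. Of the single-symbol clusters 14404 were found by Entrez number in the RefSeq table of assembly GRCh38.p14 and 28 were not, and 0 symbols changed. Where clusters shared a symbol, the one with the highest mean over all arrays stood for the gene, which left 14232 genes. TRPM1, the host gene of miR-211, and IGF2R shared their clusters with other genes and were not analysed here. miR-211 itself was not measured either, so its overexpression could not be checked in either line. Sex chromosome marker genes were not named here, but they stayed in the fit, the counts and the correlations.

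All 15 arrays entered one limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes) with 5 groups, no covariate and no filter on low values, and tests were two-sided. The prior had 4.108 degrees of freedom beside 10 residual ones, and the median standard error of a difference of groups was 0.182. A cluster counted as called at a Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons were each parental line against melanocytes, each miR-211 culture against its parent, the difference of the miR-211 effects, and A375 against WM1552C. Fixed before the data were examined were the comparisons, the tests, most alternatives, the rule for named genes, and 22 gene lists with 302 distinct genes, of which 245 were measured. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera sets a list against all other genes, so a list said to shift did so relative to them. Fry asks instead whether the members of a list changed at all.

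Named genes were the 8 largest rises and 8 largest falls per comparison among called genes in which every array of one group lay above every array of the other, up to 4 members of each list with the largest changes, a fixed set around miR-211 (KCNMA1, MITF, TGFBR2, NFAT5 and POU3F2), and the 5 largest differences per direction between the miR-211 effects. Named after their values were seen were the genes of the comparison of the parental lines, single genes that moved against their list, SOX10, GPR143, and the class II genes CIITA and CD74 in the difference of the effects.

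The procedure was tested on simulated data with known changes over 17881 clusters. For WM1552C with miR-211 it recovered 14.9%, 62.7% and 100% of changes of 0.5, 1 and 2 (log2), and for A375 with miR-211 6%, 74.6% and 100%, with 5 false calls each. The simulated noise was independent between arrays, with 1 SD per cluster for all groups. In the data the median SD ran from 0.096 in WM1552C to 0.271 in A375 with miR-211. Deviations of arrays with the same number correlated with r from -0.623 to 0.416. These shares and false calls may therefore not hold for the real comparisons. In a simulated list test over 14232 genes the 1 shifted list was called and 0 of 21 others. Correlations of changes were set beside 200 simulations of unchanged groups drawn on shared control arrays. They drew residual arrays of all groups with replacement and random signs, so 1 array could enter several groups, unlike in the data.

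Alternatives were fits on the compared arrays alone, the replicate number as a block, removal of the lowest 25% or 50% of clusters by mean, quantile normalization, centring of each array on its median, a robust prior with trend, array weights, a plain test per gene, a stricter threshold, a minimum change of 1, and leaving out each array in turn. Chosen after the data were seen were leaving out the array farthest from the middle of each group, replacing the constant of 16 by 4, removing an array-wide trend, and splitting the melanocyte arrays between the comparisons that share them. A pseudocount on the log scale was not varied because the values were logged already. A search for miR-211 seed matches was not made because no 3′ UTR sequences were held.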

Results

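Gene expression was compared between normal human melanocytes and the melanoma lines WM1552C and A375, each line as the parental culture and with miR-211 overexpressed. miR-211 is a microRNA of pigment cells that lies within the melastatin gene. The 15 exon arrays formed 5 groups of 3 and reported 17881 transcript clusters, of which 14232 distinct genes had a cluster of their own. Array medians were 7.25, 7.24 and 7.02 (log2) for melanocytes, 7.70, 7.68 and 7.75 for WM1552C, 7.67, 7.69 and 7.55 for WM1552C with miR-211, 7.41, 7.41 and 7.63 for A375, and 7.09, 7.48 and 7.32 for A375 with miR-211. The median SD of a cluster within a group was lowest in WM1552C, at 0.096, and highest in A375 with miR-211, at 0.271. Values after ± are standard errors of a log2 difference between groups of 3 arrays, and p-values are limma's, Benjamini-Hochberg adjusted. They measure only the spread between these arrays, which may be technical, because the labels do not say whether replicates were separate cultures. The number of arrays limits the precision.

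**Figure D1:**
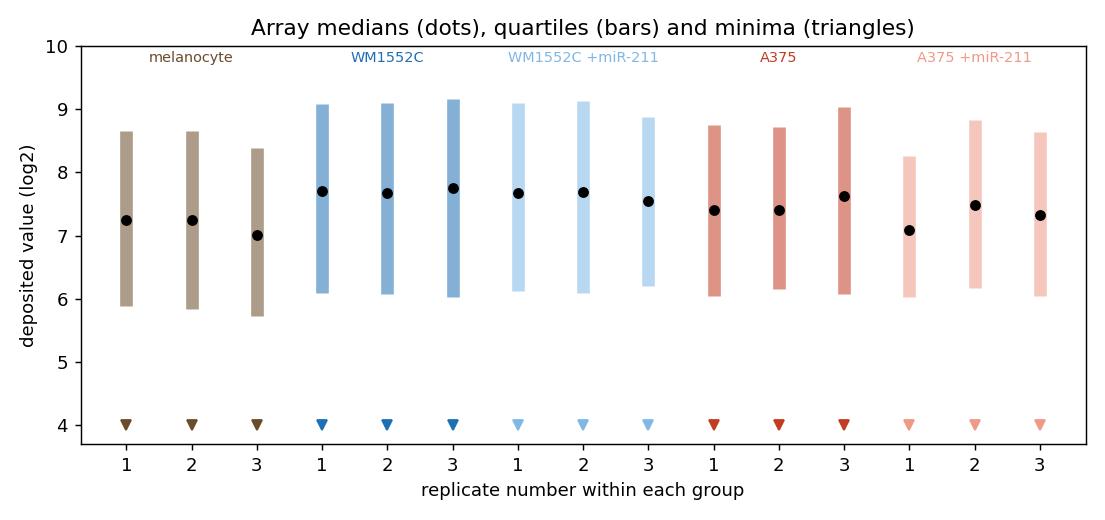
Deposited log2 values (vertical axis) of each of the 15 arrays (horizontal axis, replicate number within each group), with dots for medians, bars from the lower to the upper quartile and triangles for minima. Medians ran from 7.02 in melanocyte replicate 3 to 7.75 in WM1552C replicate 3, and every array had its minimum at 4.

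WM1552C was set against melanocytes to ask how a melanoma line differs from normal pigment cells. Pigment genes were lower in WM1552C, to very different degrees. OCA2, a melanosomal membrane protein, fell by 9.27 ± 0.12 (log2, adjusted p = 8.8e-16), and the melanosome proteins MLANA and PMEL fell by 9.2 ± 0.25 and 8.71 ± 0.14. MITF, the central transcription factor of melanocytes, fell by 3.5 ± 0.19 (adjusted p = 1.1e-09), and SOX10, a neural crest transcription factor, by 6.17 ± 0.21. GPR143, a melanosomal receptor, fell by only 1.41 and stayed at 9.27, above the array medians. In place of these, genes of connective tissue matrix were high: MFAP4, a microfibril-associated glycoprotein, rose by 8.98 ± 0.12 (adjusted p = 8.8e-16), COL3A1, the chain of type III collagen, by 7.35 ± 0.33, and LUM, a collagen-binding proteoglycan, by 7.16 ± 0.15. Other large rises were SLC14A1, a urea transporter, at 8.18, IGFBP2, an insulin-like growth factor binding protein, at 7.59, TMEM119 at 7.49, COLEC12 at 7.2 and EDIL3 at 7.17. WFDC1, DPP4, OLFM1, A2M and CELF2 fell by 8.02, 7.91, 7.9, 7.61 and 7.6.

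Of the 22 gene lists, 7 shifted in WM1552C against melanocytes. All 14 measured pigmentation genes fell (median -5.9, adjusted p = 1.5e-17, and adjusted p = 0.0059 with an estimated correlation). Of 5 Schwann and glial markers 4 fell (adjusted p = 7.4e-05, and adjusted p = 0.014 with an estimated correlation), led by S100B at -4.94 and CDH19 at -3.74. Of 9 fibroblast markers 7 rose and 1 fell (median 5.68, adjusted p = 0.00025, but adjusted p = 0.2 with an estimated correlation). Among them DCN, a small matrix proteoglycan, rose by 6.6 and POSTN, a matrix protein of fibroblasts, by 6.17, while COL1A2 fell by 1.01. Extracellular matrix genes rose in 16 and fell in 3 of 21 cases (adjusted p = 0.00022, but adjusted p = 0.43 with an estimated correlation), with COL6A3 up by 5.49 and COL5A1 by 5.31. That list and the fibroblast list share COL1A1, COL1A2 and COL3A1.

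Genes of the undifferentiated melanoma state rose in 12 of 13 cases and 1 fell (adjusted p = 2.9e-05, but adjusted p = 0.31 with an estimated correlation). They included TGFBI, a matrix protein induced by TGF-beta, at 5.59, the lysyl oxidase LOXL2 at 5.34 and the ligand WNT5A at 4.69. TGF-beta signalling genes rose in 14 of 16 cases, and in 15 adjusted over the list alone (adjusted p = 2.8e-05, but adjusted p = 0.53 with an estimated correlation). ID1 and ID3, inhibitors of differentiation, rose by 6.55 and 5.02 and the ligand TGFB2 by 3.82. The receptor TGFBR2, which is also on the list of reported miR-211 targets, differed by 0.13 ± 0.2 (adjusted p = 0.6) and turned to -0.36 after quantile normalization and -0.41 with arrays centred on their medians. Cell cycle genes rose in 14 and fell in 2 of 19 cases (adjusted p = 0.0077, but adjusted p = 0.67 with an estimated correlation), with the proliferation antigen MKI67 up by 3.58 and the topoisomerase TOP2A by 3.48. Without the 50% of clusters with the lowest signal the cell cycle list and the Schwann and glial list missed the threshold (0.069 and 0.057). All 19 cell cycle genes stayed in that test, but only 1 of the 5 Schwann and glial markers. The keratinocyte, endothelial and leukocyte lists did not shift (adjusted p = 0.47 each), though single members passed, such as KRT14 at -1.11 and CD3E at -1.24.

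The list of reported miR-211 targets missed the threshold in WM1552C against melanocytes as deposited (adjusted p = 0.071) and passed, upward, after quantile normalization (0.048) and after centring on medians (0.035), with adjusted p = 0.67 with an estimated correlation. Of its 15 measured genes 10 rose. KCNMA1, the pore subunit of a calcium-activated potassium channel, rose by 3.04 ± 0.19 (adjusted p = 5.2e-09), the osmotic stress factor NFAT5 by 2.31 and the neural transcription factor POU3F2 by 2.25, while PDK4, a kinase that inhibits pyruvate dehydrogenase, fell by 5. Part of this list, KCNMA1 included, was drawn from reports on melanoma lines such as these, so its direction is not independent evidence. Interferon response genes (adjusted p = 0.27) included BST2 at 5.56 and IFITM1 at 4.38. Cadherins and EMT factors went both ways (adjusted p = 0.47): the epithelial cadherins CDH1 and CDH3 fell by 6.4 and 5.78, and the transcription factors TWIST1 and ZEB1 rose by 5.99 and 4.48. Of 4 melanoma genes measured (adjusted p = 0.36), the cell cycle inhibitors CDKN2A and CDKN2B fell by 0.82 and 1.05 and NF1 rose by 1.15. The angiogenic factor VEGFA, of the hypoxia list (adjusted p = 0.51), rose by 4.39.

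In all, 9337 clusters passed the test in WM1552C against melanocytes, 6687 of them up and 2650 down (71.6% up). This split turned to 4649 up and 5971 down (43.8% up) after quantile normalization and to 4284 up and 8083 down (34.6% up) with arrays centred on their medians. The median change over all clusters was 0.189 as deposited, -0.157 after quantile normalization and -0.352 after centring, so small changes, deposited rises of up to about the distance between these medians included, have no settled direction.

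**Figure D2:**
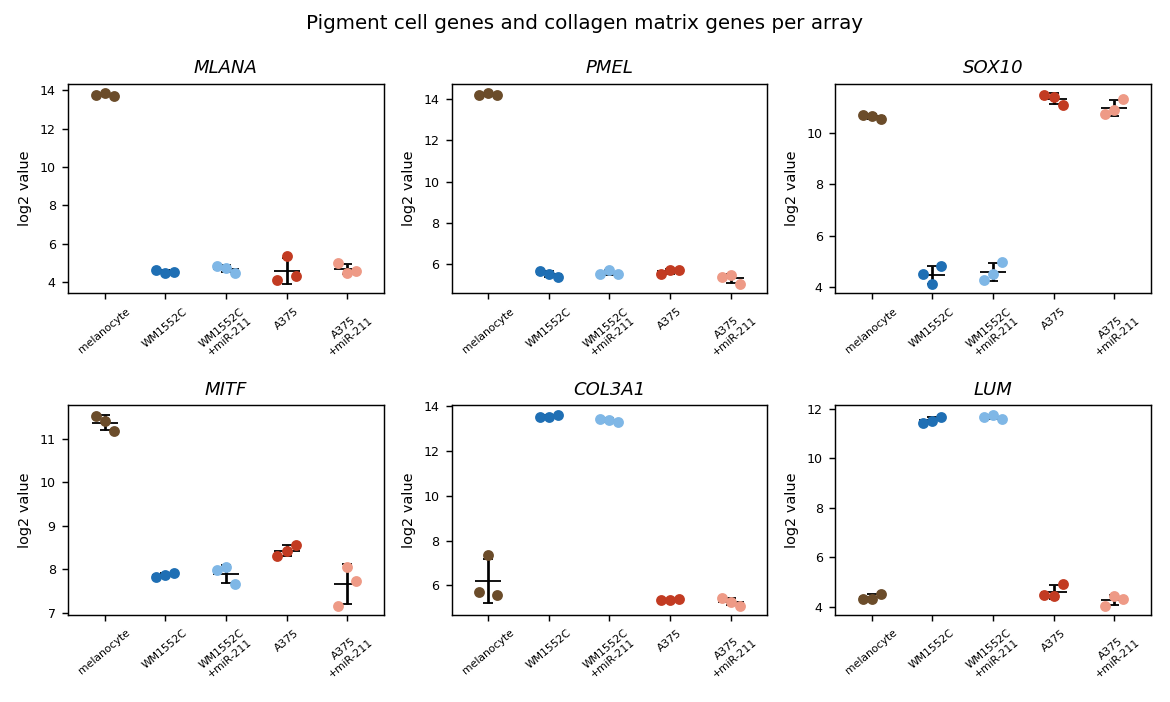
Log2 values of 6 genes (vertical axes) in the 5 groups (horizontal axes), with dots for single arrays, dashes for group means and bars for 1 SD. MLANA and PMEL lay far lower in all 4 melanoma groups than in melanocytes, SOX10 was low only in the WM1552C groups, and COL3A1 and LUM were high only in the WM1552C groups.

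A375 was set against the same melanocyte arrays. Pigment genes fell here too, but A375 kept the neural crest factor SOX10 and showed no fibroblast profile. MLANA fell by 9.15 ± 0.25 (adjusted p = 9.4e-13), the melanin enzyme TYRP1 by 8.95 ± 0.13, OCA2 by 8.87 and PMEL by 8.58, and MITF fell by 2.94 ± 0.19 (adjusted p = 1.1e-08). SERPINA3, an acute-phase protease inhibitor, rose by 8.44 ± 0.18 (adjusted p = 7.7e-14), CHRDL1, a secreted antagonist of bone morphogenetic proteins, by 7.8, the interleukin receptor chain IL13RA2 by 7.66, and CD74, the invariant chain of MHC class II, by 7.63 ± 0.19. The growth factor TGFA rose by 7.45, LOXL4 by 7.37, GTSF1 by 7.2 and HAPLN1 by 7.14. WFDC1, DPP4 and OLFM1 fell by 7.96, 7.61 and 7.53, and the histone gene H3C11 fell by 7.84, a value that is uncertain because the histone genes are near-identical.

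Of the 22 lists 10 shifted in A375 against melanocytes, and pigmentation alone kept its call with an estimated correlation. Pigmentation genes fell in 13 of 14 cases (adjusted p = 2.3e-16, and adjusted p = 0.0078 with an estimated correlation). The exception was SOX10, which rose by 0.68 but did not pass with arrays centred on their medians. Targets of p53 fell in 7 of 9 cases (adjusted p = 0.00064, but adjusted p = 0.38 with an estimated correlation), among them ZMAT3 by 2.01 and the cell cycle inhibitor CDKN1A by 1.46. Genes of the ER stress and amino acid response fell in 9 and rose in 1 of 14 cases (adjusted p = 0.0045, but adjusted p = 0.51 with an estimated correlation), with VLDLR down by 1.42 and CHAC1 by 1.15. MAPK feedback genes rose in 11 and fell in 2 of 15 cases (adjusted p = 0.0087, but adjusted p = 0.58 with an estimated correlation): the pathway inhibitor SPRY4 rose by 3.58, the transcription factors ETV4 and EGR1 by 3.12 and 2.92.

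Undifferentiated-state genes rose in 9 and fell in 2 of 13 cases in A375 (adjusted p = 0.0062, but adjusted p = 0.51 with an estimated correlation), with TGFBI at 4.25, LOXL2 at 4 and the receptor kinase AXL at 2.55, against JUN at -2.64. Cell cycle genes rose in 13 of 19 cases (adjusted p = 0.011, but adjusted p = 0.74 with an estimated correlation), MKI67 by 4.33; with arrays centred on medians 7 rose and 2 fell. Calcium-activated potassium channel genes rose in 5 of 7 cases (adjusted p = 0.013, but adjusted p = 0.17 with an estimated correlation), KCNN4 by 4.01, KCNN3 by 2.22 and KCNMA1, shared with the miR-211 target list, by 1.87. Cancer testis antigens rose in 4 of 5 cases (adjusted p = 0.013, but adjusted p = 0.17 with an estimated correlation), led by MAGEA4 at 6.53 and MAGEA10 at 3.58, members of a family of near-identical genes whose values are uncertain. Fibroblast markers fell in 5 and rose in 1 of 9 cases (adjusted p = 0.028, but adjusted p = 0.51 with an estimated correlation and 0.06 after quantile normalization), FAP by 3.81. Interferon response genes fell in 8 and rose in 4 of 21 cases (adjusted p = 0.044, but adjusted p = 0.74 with an estimated correlation and 0.076 after quantile normalization), with HERC5 at -2.25 and OAS3 at 2.38. Without the 50% of clusters with the lowest signal the cancer testis (0.15), fibroblast (0.091) and interferon (0.42) lists missed the threshold. That removal left 1 of 5 cancer testis, 5 of 9 fibroblast and 7 of 21 interferon genes, so the cancer testis value is that of a single gene.

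Antigen presentation genes did not shift as a list in A375 (adjusted p = 0.63), where the median was -0.41 and the mean 0.85: the class II genes HLA-DRA, CIITA and HLA-DPA1 rose by 5.57, 2.09 and 1.74 beside CD74, while 5 of the 12 genes fell. ERBB3, a neuregulin receptor on the Schwann and glial list (adjusted p = 0.59), rose by 4.28, and the matrix glycoprotein TNC rose by 6.4 while MMP1 fell by 5.79 in the matrix list (adjusted p = 0.19). Reported miR-211 targets had an adjusted p of 0.1, with IGFBP5, an insulin-like growth factor binding protein, up by 3.92, POU3F2 by 3.02 and NFAT5 by 2.22. TGFBR2 differed by -0.43 (adjusted p = 0.093), and passed without melanocyte replicate 3 (0.046) and without A375 replicate 3 (0.043). In total 8300 clusters passed, 5589 up and 2711 down (67.3% up), against 48.1% up after quantile normalization and 44.1% up after centring on medians. The median change of all clusters was 0.147 as deposited, -0.103 after quantile normalization and -0.17 after centring.

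Both lines against melanocytes shared 3109 rising and 1083 falling genes, where independent lists of these sizes would share 1700 and 346, and 608 genes moved in opposite directions. These overlaps were taken on the deposited scale only, where 71.6% and 67.3% of the called clusters rose in WM1552C and A375. After quantile normalization 43.8% and 48.1% rose, and after centring on medians 34.6% and 44.1%. The overlap was not recomputed on rescaled arrays, so its size and its split into rises and falls are not settled. The changes of the lines correlated across 14232 genes with Pearson's r of 0.573 and Spearman's rho of 0.564; genes are not independent replicates. Both comparisons used the same melanocyte arrays, and simulated unchanged groups against shared controls gave a mean r of 0.45 (95% of simulations between -0.323 and 0.928). The covariance was 0.8 against 0.0217 simulated. In 50 simulations without any effect the median number of genes rising in both was 0 and the highest 4849, which a single simulation gave. With the melanocyte arrays split between the comparisons, 1 against the other two, r was 0.52 to 0.576 over the 6 splits (mean 0.549).

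The parental lines were then compared directly, since their baselines enter the comparison of the miR-211 effects. A375 exceeded WM1552C in SERPINA3 by 9.13 ± 0.18, CHRDL1 by 8.61, IL13RA2 by 7.77 and SOX10 by 6.85 ± 0.21 (adjusted p = 3.6e-12), and lay below it in MFAP4 (-8.94 ± 0.12), COL3A1 (-8.19), TMEM119 (-7.81) and DCN (-7.5). Fibroblast markers were lower in A375 in 8 of 9 cases (median -6.18, adjusted p = 2.1e-08, and adjusted p = 0.029 with an estimated correlation), and Schwann and glial markers higher in 4 of 5 (median 3.42, adjusted p = 0.00013, and adjusted p = 0.029 with an estimated correlation), ERBB3 by 6.31 and S100B by 5.91. All 16 TGF-beta signalling genes were lower (adjusted p = 1.6e-06, but adjusted p = 0.51 with an estimated correlation), as were 8 of 9 cholesterol synthesis genes (adjusted p = 0.0032, but adjusted p = 0.51 with an estimated correlation), HMGCS1 by -1.85. Matrix genes were lower in 14 and higher in 5 of 21 cases (adjusted p = 0.0032, but adjusted p = 0.52 with an estimated correlation), interferon genes lower in 11 and higher in 2 of 21 (adjusted p = 0.00097, but adjusted p = 0.52 with an estimated correlation) and undifferentiated-state genes lower in 9 and higher in 3 of 13 (adjusted p = 0.034, but adjusted p = 0.64 with an estimated correlation). These last 3 lists missed the threshold without the 50% of clusters with the lowest signal (0.11, 0.3 and 0.38), which left 7 of the 21 interferon genes. The undifferentiated-state list also missed it without the farthest arrays (0.054). Of 7520 clusters past the test 39.3% were higher in A375, against 51.4% after quantile normalization and 56.3% after centring on medians, which moved the median of all clusters from -0.0128 to 0.211.

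In WM1552C with overexpressed miR-211, 6 clusters passed. HLA-DPA1 and HLA-DPB1, the chains of an MHC class II molecule, rose by 1.85 ± 0.24 (adjusted p = 0.011) and 1.05 ± 0.16 (adjusted p = 0.04). HLA-DPB1 stood at 4.02 in the parental line, at the floor of the arrays, so its rise is only a bound. TM4SF1, a tetraspanin-like membrane protein, rose by 1.75 ± 0.19 (adjusted p = 0.0048), and the secreted chaperone CLU rose by 1.17 ± 0.14 (adjusted p = 0.0097). DHCR7, the enzyme of the last step of cholesterol synthesis, fell by 0.96 ± 0.12 (adjusted p = 0.011) and the collagenase MMP13 by 0.94 ± 0.14 (adjusted p = 0.04). Cholesterol synthesis genes shifted down as a list (median -0.53, adjusted p = 4.8e-15, and adjusted p = 0.029 with an estimated correlation): 1 of 9 fell, and 5 fell adjusted over the list alone. LSS differed by -0.84, HMGCS1 by -0.82 and INSIG1 by -0.74.

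Genes of the ER stress and amino acid response also shifted down in WM1552C with miR-211 (median -0.26, adjusted p = 9.4e-05, but adjusted p = 0.57 with an estimated correlation), with none of 14 past the test and 3 adjusted over the list alone, and CHAC1 at -0.53 and PSAT1 at -0.52. Antigen presentation genes shifted up (median 0.21, adjusted p = 0.00019, but adjusted p = 0.27 with an estimated correlation), with 1 of 12 past the test and 2 adjusted over the list alone; HLA-DRA differed by 1.22 ± 0.23 (adjusted p = 0.1). Reported miR-211 targets did not shift (median -0.06, adjusted p = 0.33), and none of the 15 passed. The level of miR-211 reached in this line was not measured. KCNMA1 differed by -0.28 ± 0.19, NFAT5 by -0.18, TGFBR2 by 0.07, POU3F2 by -0.06 and MITF by 0.03, each at an adjusted p of 1. Cadherins and EMT factors missed the threshold as deposited (adjusted p = 0.16) and passed downward after quantile normalization (0.017), with adjusted p = 0.92 with an estimated correlation. For fibroblast markers (adjusted p = 0.86) the median was -0.17 and the mean -0.02 while the test leaned up. At an unadjusted p under 0.05 there were 706 clusters. That is a share of all clusters below 0.05, so no more than unchanged clusters would give on average. The median standard error was 0.182 in the joint fit and 0.118 on the WM1552C arrays alone. A plain test of each gene on its 6 arrays called 0. The 6 calls rested on all of these arrays: 0 passed without WM1552C replicate 2 or without WM1552C_miR211 replicate 1 or 2, 1 without WM1552C replicate 1 or 3, and 4 without WM1552C_miR211 replicate 3. Over these fits TM4SF1 kept its call in 3 (adjusted p up to 0.064), CLU and HLA-DPA1 in 1 (up to 0.085 and 0.11), and DHCR7, HLA-DPB1 and MMP13 in 0 (up to 0.11, 0.33 and 0.26).

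In A375 with miR-211, 635 clusters passed in the joint fit of all arrays, but 12 did when the A375 arrays were fitted alone, the same number as in WM1552C fitted alone. The median standard error was 0.212 in that fit of A375 and 0.118 in that of WM1552C, and a plain test per gene called 0 in either line. ESM1, a secreted proteoglycan of endothelial cells, rose by 3.7 ± 0.17 (adjusted p = 6.6e-08), GAP43, a protein of growing axons, by 2.29 ± 0.26, TNFRSF9, a co-stimulatory receptor, by 2.05 and the reductase CYB5R2 by 2.01 ± 0.18. The cytokine IL1A rose by 1.77, the activin antagonist FST by 1.71, RGS2 by 1.68 and the chemokine CXCL8 by 1.63 ± 0.25. IGFBP5 fell by 2.75 ± 0.25 (adjusted p = 5.3e-05), the matrix glycoprotein FN1 by 2.33 ± 0.18 (adjusted p = 1.1e-05), the methyltransferase NNMT by 2.25 ± 0.21 and PDK4 by 2.1 ± 0.3 (adjusted p = 0.0015). ATP10A, RYR2, MGST1 and B3GNT7 changed by -1.92, -1.89, -1.88 and -1.8, and the fall of MGST1 missed the threshold without A375 replicate 1 (0.066) or replicate 3 (0.073). Fitted on the A375 arrays alone, 8 of these 16 genes lost their call: GAP43 (adjusted p = 0.092), TNFRSF9 (0.069), IL1A (0.18), RGS2 (0.1), CXCL8 (0.18), PDK4 (0.13), RYR2 (0.11) and MGST1 (0.3).

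Reported miR-211 targets shifted down in A375 with miR-211 (median -0.64, adjusted p = 0.00038, but adjusted p = 0.5 with an estimated correlation): 5 of 15 fell and 8 adjusted over the list alone, which is not independent evidence because part of the list came from reports on such lines. Without the 50% of clusters with the lowest signal the list's adjusted p was 0.7, and without the array of each group farthest from its group the median was -0.29 and 2 genes fell. KCNMA1 fell by 0.81 ± 0.19 (adjusted p = 0.032) and NFAT5 by 0.71 ± 0.18 (adjusted p = 0.042), while TGFBR2 differed by -0.28 (adjusted p = 0.41) and POU3F2 by 0.08 (adjusted p = 0.82). MITF fell by 0.77 ± 0.19 (adjusted p = 0.042). On the A375 arrays alone KCNMA1 (0.35), NFAT5 (0.45) and MITF (0.44) did not pass. The call on KCNMA1 was lost without A375 replicate 2 (0.06) or 3 (0.12) or A375_miR211 replicate 1 (0.14) or 3 (0.061). NFAT5 and MITF lost theirs without each of A375 replicates 1 (0.071 and 0.081), 2 (0.068 and 0.077) and 3 (0.15 and 0.14) and A375_miR211 replicates 1 (0.17 and 0.15) and 3 (0.061 and 0.056).

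Antigen presentation genes shifted down in A375 with miR-211 (median -0.57, adjusted p = 0.00038, but adjusted p = 0.5 with an estimated correlation), with 5 of 12 falling: HLA-DRA by 1.74 ± 0.23, CIITA, the transcriptional activator of class II genes, by 1.36 ± 0.12, HLA-DPA1 by 1.32 and CD74 by 1.17 among them. Fitted on the A375 arrays alone, only CIITA of these kept its call (0.041), against 0.053 for HLA-DRA and 0.15 for HLA-DPA1 and CD74. Matrix genes shifted down (median -0.2, adjusted p = 0.0064, but adjusted p = 0.5 with an estimated correlation), with 5 of 21 falling, and 10 falling and 2 rising adjusted over the list alone. FN1 was among the falls, with the adhesive glycoprotein THBS1 at -1.27 and the proteases MMP2 at -1.23 and MMP14 at -0.87. On the A375 arrays alone FN1 kept its call (0.027), while THBS1 (0.13), MMP2 (0.11), MMP14 (0.18) and, of other lists, TGFBI (0.085), SPRY4 (0.31) and KDR (0.21) lost theirs. Undifferentiated-state genes shifted down (median -0.41, adjusted p = 0.004, but adjusted p = 0.5 with an estimated correlation), with 4 of 13 falling and 6 adjusted over the list alone, among them TGFBI at -1.56. MAPK feedback genes shifted down (median -0.35, adjusted p = 0.003, but adjusted p = 0.5 with an estimated correlation), with 3 of 15 falling and 7 adjusted over the list alone, and 0 with arrays centred on medians. SPRY4 fell by 0.66 (adjusted p = 0.026), which was lost without A375 replicate 2 (0.071) or 3 (0.075) or A375_miR211 replicate 1 (0.11). Endothelial markers shifted up (adjusted p = 0.038, but adjusted p = 0.5 with an estimated correlation and 0.15 after quantile normalization), with 1 of 7 past the test, the VEGF receptor KDR at 1.58 ± 0.26, and leukocyte markers likewise (adjusted p = 0.038, but adjusted p = 0.5 with an estimated correlation and 0.21 after quantile normalization), with 0 of 7 past the test. Without the array of each group whose median lay farthest from its group these last lists had adjusted p of 0.57 and 0.68. In that fit 3 antigen presentation genes fell (median -0.33), 1 undifferentiated-state gene (median -0.21) and 1 MAPK feedback gene, and these lists kept their calls. Cell cycle genes did not shift as deposited (adjusted p = 0.49) but passed upward in that fit (0.0023) and after quantile normalization (0.026), with adjusted p = 0.99 with an estimated correlation. Without the 50% of clusters with the lowest signal the antigen presentation (0.13), matrix (0.14), MAPK feedback (0.058) and leukocyte (0.11) lists missed the threshold. Of the 7 leukocyte markers only 1 stayed in that test.

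In A375 with miR-211, 635 clusters passed, 62 up and 573 down (9.76% up), and a change of at least 1 was reached by 25 up and 145 down. The median of all clusters was -0.132, and it moved to 0.0137 after quantile normalization, with 182 up and 426 down (29.9% up), and to 0.0523 after centring on medians, with 173 up and 379 down (31.3% up). Relative to centred arrays the list medians were -0.45 for miR-211 targets, -0.38 for antigen presentation, -0.23 for the undifferentiated state, -0.17 for MAPK feedback and -0.02 for matrix genes. The count was 12 with the A375 arrays alone, 336 without A375 replicate 1, 288 without A375 replicate 3, 259 without A375_miR211 replicate 1, 2037 without A375_miR211 replicate 2, and 256, of which 68% fell, without the array of each group whose median lay farthest from its group.

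**Figure D3:**
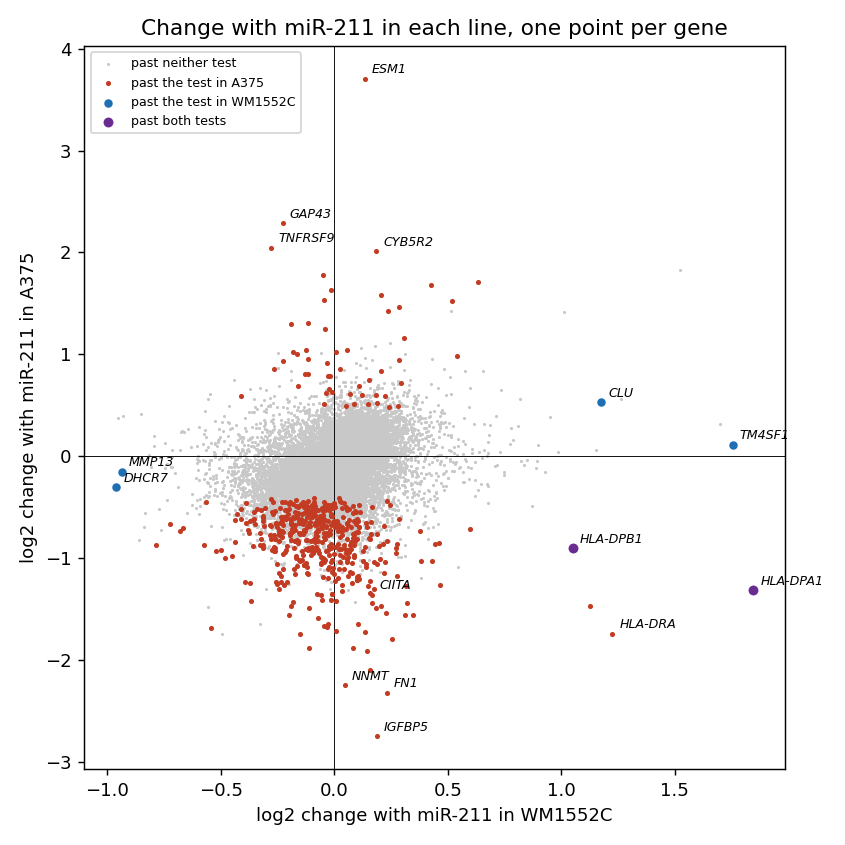
Log2 change with miR-211 in WM1552C (horizontal axis) and in A375 (vertical axis), one dot per gene, coloured by which comparison the gene passed. Of the genes past the test in A375, 54 rose and 472 fell, a split that shrinks when arrays are rescaled, and HLA-DPA1 and HLA-DPB1 passed in both lines with opposite signs.

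The level of miR-211 was not measured, so it may differ between the lines. The difference between the miR-211 effects of the lines, A375 minus WM1552C, was tested directly. It was largest for ESM1 at 3.57 ± 0.24 (adjusted p = 1.2e-05), GAP43 at 2.52, TNFRSF9 at 2.32 and CYB5R2 at 1.82 on the positive side, and for HLA-DPA1 at -3.16 ± 0.34 (adjusted p = 0.00057), HLA-DRA at -2.97 ± 0.33 (adjusted p = 0.00057), IGFBP5 at -2.94 ± 0.36, MOXD1 at -2.6 ± 0.41 and FN1 at -2.56 ± 0.25 (adjusted p = 0.00028) on the negative side. ADAMTS1, a matrix protease, differed by 1.58 ± 0.29 (adjusted p = 0.032). Its call was lost in 9 of the 12 fits that left out 1 array (adjusted p up to 0.11), and kept only without A375 replicate 3 or A375_miR211 replicate 1 or 2. HLA-DPA1 and HLA-DPB1 were the genes called in both lines, up in WM1552C and down in A375, where independent lists would share 0.133 genes of that kind. As chains of the same class II molecule they are not independent genes, so that number overstates the contrast. The difference was -1.53 ± 0.17 for CIITA and -1.45 ± 0.27 for CD74 (adjusted p = 0.03), and that of CD74 was called in only 3 of the 12 fits that left out 1 array. In WM1552C neither passed, with changes of 0.17 and 0.28.

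Antigen presentation genes carried the list with the lowest p for this difference (median -0.73, adjusted p = 1.3e-08, but adjusted p = 0.066 with an estimated correlation), with 4 of 12 past the test and 5 adjusted over the list alone. The difference was also negative for matrix genes (median -0.3, adjusted p = 2.2e-05, but adjusted p = 0.45 with an estimated correlation), undifferentiated-state genes (median -0.5, adjusted p = 0.00058, but adjusted p = 0.45 with an estimated correlation) and reported miR-211 targets (median -0.44, adjusted p = 0.001, but adjusted p = 0.55 with an estimated correlation). Of these lists 3 of 21, 1 of 13 and 2 of 15 genes passed the test. For MAPK feedback genes it was negative too (median -0.32, adjusted p = 0.048, but adjusted p = 0.56 with an estimated correlation and 0.11 after quantile normalization). Without the 50% of clusters with the lowest signal the target and MAPK feedback lists missed the threshold (0.55 and 0.22). For cholesterol synthesis genes the difference was positive (median 0.31, adjusted p = 2.2e-05, but adjusted p = 0.33 with an estimated correlation), none past the test and 2 adjusted over the list alone. Their median change with miR-211 was -0.31 in A375 and -0.53 in WM1552C. For cell cycle genes (adjusted p = 0.048, but adjusted p = 0.7 with an estimated correlation) and ER stress genes (adjusted p = 0.045, but adjusted p = 0.55 with an estimated correlation) the test leaned up while the medians were -0.03 and -0.06 and the means 0.05 and 0.09; without the farthest arrays the medians turned to 0.28 and 0.16, and that of miR-211 targets was -0.24. In total 83 clusters passed, 13 up and 70 down (15.7% up), against 32.1% up after quantile normalization and 27.9% up after centring on medians. Leaving out any one WM1552C or WM1552C_miR211 array left 33 to 42 calls, and leaving out A375 replicate 3 or 1 left 53 or 55, while 158 passed without A375_miR211 replicate 2.

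**Figure D4:**
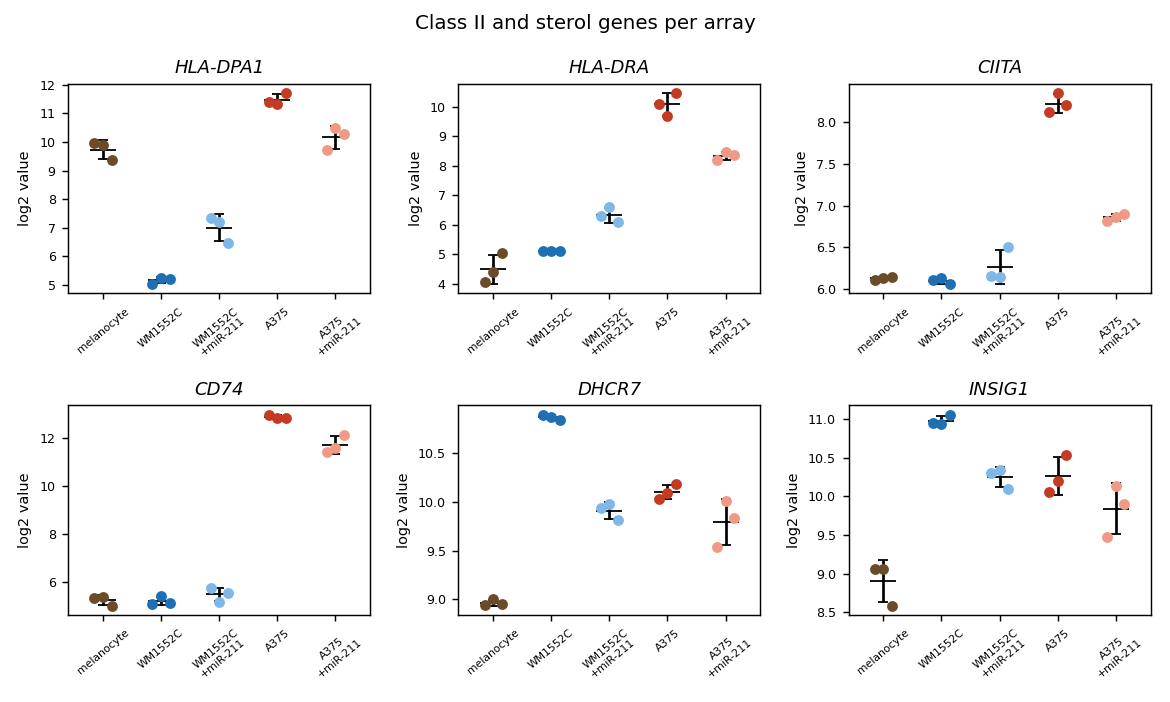
Log2 values of 4 class II genes and 2 sterol genes (vertical axes) in the 5 groups (horizontal axes), with dots for single arrays, dashes for group means and bars for 1 SD. HLA-DPA1 had means of 5.16 in WM1552C, 7 with miR-211, 11.5 in A375 and 10.2 with miR-211, and DHCR7 lay lower with miR-211 on all WM1552C arrays.

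The miR-211 effects of the lines, which share no arrays, correlated across 14232 genes with r = 0.283 and rho = 0.364. The correlation was 0.047 without replicate 3 of each group and 0.419 without replicate 2. Simulated unchanged groups gave r between -0.865 and 0.772 in 95% of cases, a range that held the observed value. That simulation could place 1 residual array in both lines, which may widen the range, so it does not decide the agreement. Independent noise gave a mean r of 0.003. To ask whether miR-211 moved a line towards melanocytes, its effect was set against the difference of melanocytes from the parental line. Pearson's r was 0.219 for WM1552C and 0.225 for A375, and rho was 0.282 and 0.265. Because both differences used the parental arrays, simulated unchanged groups already gave a mean r of 0.502 and 0.447. The covariance was 0.0498 for WM1552C and 0.0859 for A375, both inside the range of 95% of simulations (-0.0126 to 0.118 with a mean of 0.026, and -0.0148 to 0.0973 with a mean of 0.0224). These ranges came from the same simulation and do not decide a shift. Independent noise gave a mean covariance of 0.0217 for both. With the parental arrays split between the differences, r was 0.055, 0.139 and 0.263 for WM1552C and 0.153, 0.135 and 0.111 for A375. For WM1552C r turned to -0.041 without replicate 3.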

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

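Of the tests in this part, those of array scaling and of the share of A375 cells that HLA-DPB1 needs were chosen only after the result was seen.

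The effect of miR-211 differed between A375 and WM1552C in a direct test for 83 clusters. Of 100 random regroupings of arrays within the lines, drawn from 200, 2 gave as many calls, the real one included, a share under 0.05. Others gave 87, 78 and 72 calls, close to or above the real count, while most gave 0. The regrouping moved the arrays of both lines at once, so some regroupings could keep the real A375 groups. The share therefore does not exclude chance for a difference between the lines. Single genes that passed were ESM1 (3.57), GAP43 (2.52), TNFRSF9 (2.32), CYB5R2 (1.82), ADAMTS1 (1.58), IGFBP5 (-2.94), MOXD1 (-2.6) and FN1 (-2.56), as log2 differences of A375 minus WM1552C. Lists that passed had medians of -0.44 for reported miR-211 targets, -0.5 for the undifferentiated melanoma state, -0.03 for the cell cycle, -0.3 for the extracellular matrix, -0.73 for antigen presentation, -0.32 for MAPK feedback, -0.06 for ER stress and 0.31 for cholesterol synthesis, and with an estimated correlation none of them passed.

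Of the MHC class II genes, HLA-DPA1 (difference -3.16) and HLA-DPB1 passed in opposite directions in the lines, whereas HLA-DRA (difference -2.97), CIITA and CD74 fell in A375 without passing in WM1552C. Scaling of the arrays was argued against, since both, 2 of 2, were still called up in WM1552C and down in A375 after quantile normalization and after centring. The calls were less firm to other changes: on the A375 arrays alone the falls of HLA-DPA1 (adjusted p = 0.15) and HLA-DPB1 (0.23) did not pass, and leaving out single arrays took the rises in WM1552C up to 0.11 and 0.33; HLA-DPB1 rose there from 4.02, the floor of the arrays, so its size is only a bound. A375 cells among the WM1552C cultures with miR-211 were argued against as well: HLA-DPA1 would need a share of 8.37%, and 20 genes specific to A375 allowed a median share of 0.0644%, which is 0.77% of the share HLA-DPA1 needs and 1.4% of the share HLA-DPB1 needs. A response to miR-211 that differs between the lines may remain, and so may an unequal level of miR-211, which was not measured. Any other difference between single cultures may remain too, which the design does not separate.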

How the results depend on the processing

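Leaving out the farthest arrays, the replaced constant, the removed trend and the split of the melanocyte arrays were alternatives chosen only after the data were seen. The cause of the moves below was not tested, except that stricter thresholds and fewer clusters leave fewer calls by construction.

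For WM1552C against melanocytes 6068 clusters passed without the lowest 50% of clusters and 4868 with a change of at least 1, and for A375 against melanocytes 5461 and 4166. For WM1552C with miR-211 (6 calls) the count was 12 on the compared arrays alone, 12 after quantile normalization, 28 after centring, 2321 with array weights, 0 with a plain test per gene, 2 at a threshold of 0.01, and 0 to 4 leaving out each array. For A375 with miR-211 (635 calls) it was 12 on the compared arrays, 5665 with array weights, 0 with a plain test per gene against 3860 clusters at limma's unadjusted p under 0.05, 256 without the farthest arrays, 1349 with the trend removed, 175 at a threshold of 0.01, 170 with a change of at least 1, and 259 to 2037 leaving out each array. For the difference of the effects (83 calls) it was 52 on the compared arrays, 38 without the lowest 50%, 159 after quantile normalization, 172 after centring, 4195 with array weights, 43 with a plain test, 53 without the farthest arrays, 47 with the constant replaced, 28 at 0.01, and 33 to 158 leaving out each array. For A375 against WM1552C (7520) it was 4943 without the lowest 50%, 11305 with array weights and 3535 with a change of at least 1. The array weights did not converge, so their counts say little.

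The list counts with fry answer another question than those with camera, because fry does not set a list against the other genes. Where many clusters are called, fry can pass most lists. Of the 22 lists, 7 passed for WM1552C against melanocytes, against 2 with an estimated correlation and 16 with fry. The same counts were 10, 1 and 18 for A375 against melanocytes, 3, 1 and 1 for WM1552C with miR-211, 8, 0 and 3 for the difference, and 7, 2 and 18 for A375 against WM1552C. For A375 with miR-211 7 passed, 0 with an estimated correlation, 6 with fry and 3 without the lowest 50% of clusters. Correlations moved as follows: the effects of miR-211 between lines, 0.047 to 0.419 leaving out each replicate number; the shift of WM1552C towards melanocytes, -0.041 to 0.327; the shift of A375, 0.19 to 0.305, 0.147 without the lowest 50% and 0.133 with the parental arrays split. Against melanocytes in WM1552C, TGFBR2 reversed to -0.36 after quantile normalization and -0.41 after centring, and DSP, TEK and PECAM1 reversed to -0.48, -0.37 and -0.18 after centring. Over all named genes leaving out single arrays kept 2385 results, lost 94 and added 29.

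With the replicate number as a block 8970, 7961, 4, 374, 47 and 7133 clusters passed for WM1552C and A375 against melanocytes, WM1552C and A375 with miR-211, the difference, and A375 against WM1552C. The numbers did not pair the samples: 11 of 30 pairs of arrays with the same number deviated together with r over 0.1 (from -0.623 to 0.416), and 1 of 15 arrays was closest to its own number. Random splits of 3 against 3 arrays number 10, too few for a share under 0.05: real and highest other counts were 9337 and 0, 8300 and 0, 6 and 0, 635 and 14, and 7520 and 0 for the comparisons of 2 groups, and the real split was the 1 that gave as many in each. A pseudocount of 16 on the log scale and a test of miR-211 seed sites were not run. No detection flags were held, so genes near the minimum of 4 are measured against an unknown background.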

Other observations

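Of the tests in this part, those of overall brightness, of the farthest arrays and of the fibroblast markers were chosen only after the result was seen. The removal of an array-wide trend was also an alternative chosen after the data were seen.

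Single genes outside the lists that passed also changed in A375 with miR-211. The cell cycle factor E2F1 fell by 0.67 ± 0.14 (limma, adjusted p = 0.02), a call lost without A375 replicate 1 (0.087) or A375_miR211 replicate 1 (0.084). The p53 target ZMAT3 fell by 0.82 ± 0.16 (adjusted p = 0.014), a call lost without A375 replicate 3 (0.059). PTGES, an enzyme of prostaglandin synthesis, fell by 1.47. With the A375 arrays alone 10 genes with a single symbol passed: B3GNT7, FN1, IGFBP5, FST, ESM1, PTGES, NNMT, CYB5R2, ATP10A and CIITA. Of the 16 largest changes named, 8 passed in that fit and 15 in each of the 6 fits that left out 1 array.

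Fibroblast genes were high in WM1552C. Fibroblasts mixed with SOX10-positive tumour cells were argued against for the genes chosen, SOX10, S100B, CDH19 and EDNRB. These had a median of 2.33% of their melanocyte signal (from 1.19% for EDNRB to 7.5% for CDH19), with nothing taken off for background. They were picked with their values known. MITF and GPR143 of the pigmentation list fell less. Of the glial list, ERBB3 changed by -2.12 to -1.98 and NGFR by -1.13 to -0.89 over the fits leaving out 1 array. For normal fibroblasts in place of the line, MAGEC1 and MAGEA10 lay at least 4.43 above melanocytes, past the bound set against that explanation. These were the 2 of 5 measured cancer testis genes that rose, 3 did not pass, and the list did not shift (camera, adjusted p = 0.22). They were picked with their values known, so the bound was met in advance and does not exclude normal fibroblasts. A signal of MAGEA10 taken from its near-identical relatives would still be one of the MAGE family. Fibroblasts beside SOX10-negative tumour cells and such tumour cells alone cannot be told apart, because both may give these values and the lowest of the 9 fibroblast markers, COL1A2 at -1.01, decides neither.

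In A375 with miR-211 far more genes fell than rose. With an array-wide trend shared with other groups removed, 16 of 16 of the largest changes still passed. That says little against the trend, because the removal weakened 0 results of the named genes and raised the calls from 635 to 1349. For the excess of falls the trend stays open too. The removal leaves each array's mean level, so 89.8% of falls after it decides nothing. The single array A375_miR211 replicate 1 was argued against as the source of the high share of falls, since falls were 83.4% of calls without it. The calls themselves dropped from 635 to 259 without it, against 288 without A375 replicate 3. In the difference of the effects rises went from 15.7% to 32.9% of calls without it, so a part played by this array is not excluded. The arrays farthest from their groups and overall brightness cannot be told apart from a true excess of falls: falls were 68% of calls without those arrays and 68.7% with arrays centred on medians, both between the bounds set for the tests. A repressive effect of the microRNA may contribute, and it was not tested on seed sites.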
